A study of Mus musculus x Mus spretus and Mus musculus and Mus spretus with 83 samples.

How the data were processed

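RNA was measured in the tail epidermis of 83 mice with Affymetrix 3-prime expression arrays of mouse design, 1 array per mouse. Of these mice, 71 came from a backcross in which F1 hybrids of Mus spretus and the inbred strain FVB/N were mated to FVB/N; they had been given the carcinogen DMBA once (25 µg per mouse) and the tumor promoter TPA for 20 weeks on the back, and their papillomas were counted. The remaining 12 mice were untreated, with 4 each of FVB, Spretus and F1. The labels give each mouse a group, and for the backcross a papilloma number, which were used as given. Sex, age at sampling and hair cycle stage are not given in the labels used here.

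The deposited values are log2 expression values of 45101 probe sets, made with RMA per the submitters' processing notes; the version is not given in the sources used here. RMA subtracts background, makes the distributions of a set of arrays equal and summarises the probes of a probe set. The column medians showed that the arrays had been scaled as separate sets. The median was 4.26 ± 0.03 (SD, n = 71) in the backcross, against 5.27 ± 0.01 in FVB, 5.29 ± 0.02 in F1 and 5.36 ± 0.03 in Spretus (n = 4 each). Between the backcross and the mean of FVB and F1 the median gene differed by -0.89 on the log2 scale, with an SD over genes of 0.44. Tests were therefore made only among the untreated arrays or only among the backcross arrays. The planned test of the treated backcross against untreated mice was not made, since treatment, genotype and scaling all differ between these sets and age may differ. Levels relative to the median over genes are given in its place.

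Probe sets were named from the annotation table supplied with the array. A single gene symbol was listed for 34945 probe sets, several for 932 and none for 9160, and 64 were controls. Each of the 18193 genes with a probe set of its own was represented by the probe set with the highest mean over the 4 groups, and the 30% of genes with the lowest level were left out, which left 12735 genes. Of these, 7580 had over 1 probe set, and where probe sets of a named gene differed in direction this is stated. The arrays were designed on the sequence of laboratory mice, so a base difference in Spretus can lower the signal of a probe without a change in RNA.

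Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust estimation), with Benjamini-Hochberg adjustment over the genes of a comparison and calls at an adjusted p under 0.05. The 4 strain comparisons used the 12 untreated arrays in a single fit. In the backcross the slope on log2(papillomas + 1), on Lgr5 and on Vdr was tested over 71 mice. All tests are two-sided. Lists of genes (25 in all, fixed before the data were examined) were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation. Pearson and Spearman correlations have p-values from 100000 permutations, so that 1e-05 is the smallest they can give. Beside the fits, 2 clusters of mice per gene were sought with mclust 6.1.1. Figures were drawn with matplotlib 3.10.9.

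The rule for named genes was written before the data were examined. For Spretus against FVB and for F1 against the mean of its parents it takes the 8 called genes with the largest difference in each direction, then the member with the smallest p from up to 12 lists if called. For papilloma number and the seed genes it takes the 10 genes with the smallest p in each direction, called or not, then 1 gene from each of 12 lists. Lgr5 and Vdr are always included, and genes with clone or predicted-gene symbols are skipped. For the treated backcross, where nothing was tested, the 8 largest level differences in each direction were taken. A gene mentioned outside this rule is marked as chosen after its values were seen.

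The fits were tested on simulated data with the real gene means and spreads and 200 changed genes of the 12735. For Spretus against FVB, 84% of the genes changed by 1 log2 unit and 24% of those changed by 0.5 were called, and 2.56% of all calls were unchanged genes. For papilloma number, 88% of genes simulated at a correlation of 0.5, 52% at 0.4 and 12% at 0.3 were called. The 200 planted genes ease the adjustment, so for papilloma number these shares are too high if few genes are related. Among the real genes Msl2, at r = -0.494, was not called. The number of arrays limits the precision. Closely alike arrays were looked for, and the closest pair, F1 1 and F1 4 (r = 0.99), shared 40 identical values of 45101, so all arrays were kept as separate samples.

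Replicate numbers are shared by the 3 untreated groups in the sample titles, with nothing said of what they mark. Deviations from the group means correlated between F1 and Spretus arrays of the same number at 0.34, 0.15, 0.48 and 0.40, and all 4 lie over the limit of 0.1 set for treating numbers as pairs. For FVB with F1 they ran from -0.46 to 0.19 and for FVB with Spretus from -0.47 to 0.13, so those numbers were not treated as pairs. Alternatives tried include equal array medians, quantile normalization, other filters on dim genes, the mean over probe sets, every probe set by itself, eBayes without trend, the replicate block, all 4 groups in a single fit, each untreated array left out in turn, and covariates for Xist, muscle markers, RNA quality and principal components.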

Results

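Tail epidermis was profiled in 71 mice of a Spretus by FVB backcross, treated on the back with DMBA and TPA, and in 4 untreated mice each of FVB, Spretus and their F1 hybrid. Mus spretus is a wild-derived species and FVB a laboratory strain; the crossing and tumor treatment address the genetics of skin inflammation and tumor susceptibility. The arrays measured 12735 genes above the level filter. Of the 71 backcross mice, 20 had no papilloma and 13 had over 10. The median was 3 papillomas, the mean 5.44 ± 6.73 (SD, n = 71) and the highest number 35. Differences are given on the log2 scale, where 1 unit is a 2-fold difference.

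Untreated Spretus tail epidermis gave far lower signals of hair keratin genes than FVB, and higher signals of melanocyte and skeletal muscle genes. Of 35 measured hair follicle keratins and regulators, 31 were lower in Spretus and 1 was higher, with a median of -4.10 relative to the median gene (camera adjusted p = 1.01e-24; adjusted p = 0.199 with an estimated correlation). Krtap16-3, a keratin-associated protein of the hair shaft, measured 12.02 ± 0.76 in FVB and 3.39 ± 0.46 in Spretus (SD, n = 4 each), and Krtap15 measured 11.89 ± 0.77 against 3.86 ± 0.65. All 10 melanocyte markers were higher in Spretus, with a median of +2.44 (camera adjusted p = 1.57e-07; adjusted p = 0.199 with an estimated correlation); Mlana rose from 7.66 ± 0.25 in FVB, an albino strain, to 11.20 ± 0.23. All 19 skeletal muscle markers were higher, with a median of +4.96 (camera adjusted p = 1.55e-08; adjusted p = 0.916 with an estimated correlation), and Acta1, the actin of skeletal muscle, rose from 6.21 ± 1.33 to 12.82 ± 0.33.

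Outside these groups, the largest single differences included Ces1h, a carboxylesterase, which was higher in Spretus by at least 6.48 ± 0.26 (SE; limma adjusted p = 3.34e-09), and Wfdc17, lower by -7.24 ± 0.25 (adjusted p = 3.16e-09). The remaining genes with the largest rises were Myl2, Myh7, Myot, Tnnc2, Mb and Klhl41, all muscle genes, at 5.71 to 6.86. The remaining largest falls were Krtap8-1, Krtap19-3, Krtap7-1, Krtap19-9b and Krtap21-1, at -8.04 to -7.25. Where the lower of the 2 levels is near the array background the difference is a lower bound and the order of such genes is not measured. This holds for Krtap16-3, Krtap15, Krtap19-3 (3.72 in Spretus), Krtap7-1 (4.39) and Krtap19-9b (4.62), and for Ces1h (4.16 in FVB), Myl2 (4.21), Myh7 (4.57), Myot (3.51) and Klhl41 (4.01). Stfa3, a stefin of the cysteine protease inhibitor family, differed by -5.02 ± 0.40 (adjusted p = 3.77e-06). Gstp1, a glutathione transferase, was higher by 2.22 ± 0.12 (adjusted p = 2.07e-08), and Stat2, a transducer of interferon signals, by 1.81 ± 0.12 (adjusted p = 9.72e-08). Lower in Spretus were Elovl6, a fatty acid elongase, at -2.75 ± 0.19, the proliferation marker Mki67 at -1.76 ± 0.22, the pericyte receptor Pdgfrb at -2.49 ± 0.41, and Lyz1, a lysozyme, at -2.57 ± 0.52 with 2 of its 3 probe sets in that direction. Cldn5, of endothelial junctions, was higher by 0.81 ± 0.27. Vdr, the vitamin D receptor, measured 8.98 ± 0.10 in FVB and 7.85 ± 0.17 in Spretus (difference -1.28 ± 0.10, adjusted p = 2.35e-06). Lgr5, a marker of follicle stem cells, measured 7.42 ± 0.13 and 6.08 ± 0.36 (difference -1.49 ± 0.17, adjusted p = 3.54e-05), but its other, dimmer probe set went the opposite way.

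In all, limma called 5694 of 12735 genes between Spretus and FVB, 3643 higher and 2051 lower, of which 750 and 725 differed at least 2-fold before the shift was taken off. The median gene was 0.15 higher in Spretus; the differences above are relative to it, and with equal array medians the calls were 2676 higher and 2372 lower. The other 3 lists that passed camera were lower in Spretus. Of 18 sebaceous gland and lipid genes 8 were lower and 2 higher (adjusted p = 0.916 with an estimated correlation). Of 16 follicle stem cell markers 8 were lower (adjusted p = 0.953), and of 19 fibroblast markers 4 (adjusted p = 0.956). Where a called gene had another probe set above the filter, 73.1% of the 3990 other probe sets had the same sign. The share was 76.7% for genes higher in Spretus and 67.3% for genes lower, where probe mismatch can also lower a signal. With the mean muscle marker level as a covariate, chosen after seeing the data, the calls came to 567, and with all 4 groups in a single fit to 3496.

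**Figure D1:**
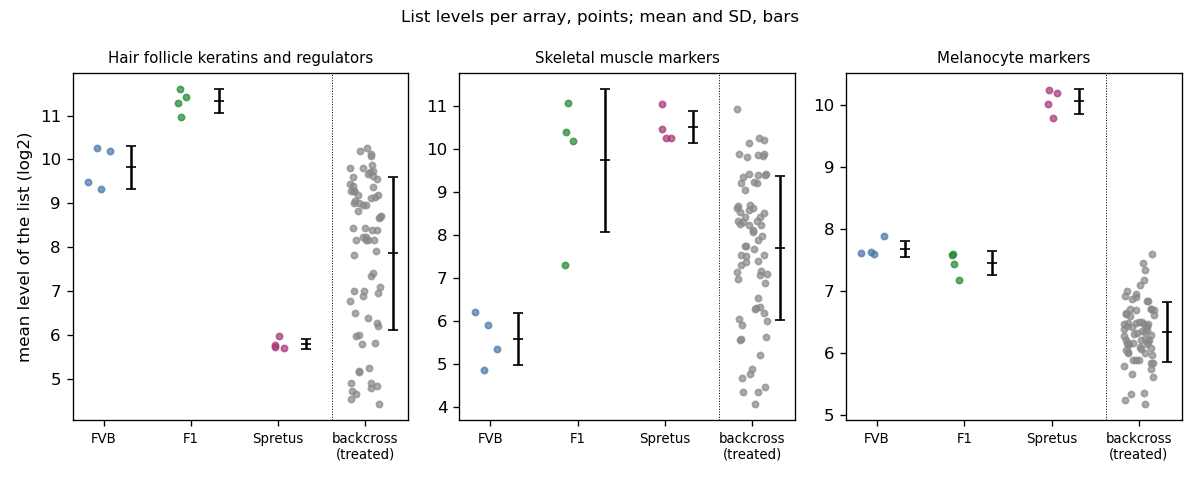
Mean log2 level of 3 gene lists per array (points) with the mean and SD of each group (bars), for 4 FVB, 4 F1, 4 Spretus and 71 treated backcross arrays; the dotted line parts the backcross, which was scaled separately, so its height is not comparable. The hair follicle level was 9.32 to 10.26 in FVB, 10.97 to 11.61 in F1 and 5.71 to 5.97 in Spretus.

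F1 hybrids expressed the hair genes at or above the FVB level. Of the 35 hair follicle genes, 26 were higher in F1 than in FVB and none was lower, with a median difference of 1.74 (camera adjusted p = 4.11e-19; adjusted p = 0.298 with an estimated correlation). Against Spretus, 33 were higher in F1 and 1 lower (median 6.14, camera adjusted p = 1.13e-42; adjusted p = 0.0690 with an estimated correlation). Muscle markers were higher in F1 than in FVB in 18 of 19 cases (median 4.43, camera adjusted p = 1.73e-16; adjusted p = 0.436 with an estimated correlation), and their mean level was 5.58 ± 0.60 in FVB, 9.74 ± 1.66 in F1 and 10.51 ± 0.38 in Spretus (n = 4 each). Of the 10 melanocyte markers, 9 were lower in F1 than in Spretus (median -3.06, camera adjusted p = 1.68e-10; adjusted p = 0.0760 with an estimated correlation), whereas 1 was higher and 2 were lower in F1 than in FVB. Of 32 cornified envelope and barrier genes, which build the outer skin layer, 7 were lower in F1 than in FVB (camera adjusted p = 4.16e-05; adjusted p = 0.784 with an estimated correlation) and 18 lower and 2 higher than in Spretus (camera adjusted p = 0.00672; adjusted p = 0.673). In the circadian list 3 of 17 genes, and in the stress keratin and hyperplasia list 2 of 14, were lower in F1 than in FVB (camera adjusted p = 0.0158 and 0.0278, the latter 0.0521 with the replicate block; adjusted p = 0.298 and 0.784 with an estimated correlation). The fibroblast and the endothelial and blood lists passed camera upward against FVB with no member called (adjusted p = 0.886 and 0.786 with an estimated correlation).

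The counts were 1794 genes between F1 and FVB (1129 higher and 665 lower in F1) and 3844 between F1 and Spretus (1576 higher, 2268 lower; 1780 and 1554 with equal array medians). Without FVB replicate 3 the first count was 1160, and with all 4 groups in a single fit it was 110, against 1567 for F1 and Spretus. With the muscle marker level or the level of Xist as a covariate, both chosen after seeing the data, it was 21 and 1147. Xist, the RNA of the inactive X chromosome of females, ran from 11.98 to 12.29 in F1, 5.64 to 12.12 in FVB and 5.63 to 12.66 in Spretus. The Y-linked Eif2s3y ran from 3.05 to 3.44 in F1, 3.04 to 9.53 in FVB and 3.34 to 8.97 in Spretus. By these genes every F1 mouse was female, while FVB and Spretus held both sexes. Sex is therefore unbalanced in each comparison with F1. It was also unevenly mixed between the parents. Eif2s3y was 8.93, 8.80, 3.34 and 8.97 in Spretus 1 to 4, and 9.53, 9.34, 3.16 and 3.04 in FVB 1 to 4. Among the backcross arrays, number 10 had both genes high (Xist 9.13, Eif2s3y 7.92) and was kept. Against Spretus, fibroblast markers (8 of 19 higher in F1), cell cycle genes (6 of 25), sebaceous gland and lipid genes (10 of 18, with 1 lower) and follicle stem cell markers (8 of 16, with 1 lower) also passed camera, at an adjusted p of 0.673, 0.673, 0.595 and 0.595 with an estimated correlation.

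Most genes that differed between the parents lay between them in F1. Among the 1475 genes called at least 2-fold apart, F1 lay between the parental means for 82.9%, at a median position of 0.375 on a scale from FVB at 0 to Spretus at 1. The position was 0.466 for the 750 genes higher in Spretus and 0.286 for the 725 lower; FVB arrays enter both differences of this ratio. Departures from the mean of the parents were called for 1156 genes, 664 above and 492 below. That mean is taken over log2 levels. It lies below the mean of the linear signals, by more the further apart the parents are, so part of a large upward departure comes from the scale. The 8 largest upward departures were all hair genes, 5.05 to 5.46 above the mean, with Spretus levels of 3.39 to 5.25. Most of these are near the array background, so the departures are lower bounds and their order is not measured. They were Krtap5-2, Krtap15, Krtap16-3, Krtap19-1, Krtap11-1 and the keratins Krt33a, Krt86 and Krt25. In the hair list 33 of 35 genes lay above and 1 below (median 3.87, camera adjusted p = 1.03e-56; adjusted p = 0.0274 with an estimated correlation), among them Krt82 by 4.51 ± 0.23 (SE). For such members, too, the departure is a lower bound where the Spretus level is near the array background. Against the mean of the linear parental signals, F1 lay a median of 2.73 above over the 29 hair list members at least 2-fold apart. Pigment genes took most places at the other end. Of 10 melanocyte markers 8 lay below the mean (median -1.63, camera adjusted p = 2.19e-12; adjusted p = 0.0465 with an estimated correlation). Tyrp1 (-2.32 ± 0.17), Tyr (-2.22 ± 0.15), Pmel (-2.15 ± 0.20), Dct (-2.11 ± 0.18), Mlana (-1.95 ± 0.15) and the melanocortin receptor Mc1r (-1.93 ± 0.25) had limma adjusted p-values from 1.19e-06 to 0.000333. The chemokine Cxcl13 lay lowest, at -3.50 ± 0.86 (adjusted p = 0.0273), but its FVB level had an SD of 2.48. Cfap57, of motile cilia, lay at -1.85 ± 0.35.

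Smaller departures, again from the mean of log2 levels, were called for single genes of other lists. Against the mean of the linear signals the upward ones are smaller and the downward ones larger. Lgr5 lay above the mean of the parents by 1.06 ± 0.14 (SE; limma adjusted p = 0.000446), Vdr by 0.69 ± 0.09, the clock output gene Dbp by 1.51 ± 0.18, Elovl6 by 1.10 ± 0.17, Mki67 by 0.87 ± 0.19, Wnt11 by 0.73 ± 0.14, Col5a1 by 1.31 ± 0.30 and the muscle myosin Myh2 by 3.07 ± 0.61. Asprv1, a protease of the cornified layer, lay below it by -0.75 ± 0.10, Lamb3, of the basement membrane, by -0.59 ± 0.14, and Nlrc5, an activator of class I genes, by -1.35 ± 0.24. The other lists that passed camera were these. Upward were muscle (4 of 19 called), fibroblast (4 of 19), cell cycle (2 of 25), follicle stem cell (4 of 16), sebaceous (6 of 18, with 1 lower) and Wnt genes (6 of 28, with 2 lower). Downward were cornified envelope (8 of 32, with 1 higher), basal epidermis (1 of 12) and antigen presentation (1 of 15); their adjusted p ran from 0.454 to 0.623 with an estimated correlation. Without F1 replicate 3 the count of departures fell from 1156 to 693, with all 4 groups in a single fit it was 198, and with the level of Xist or of muscle as a covariate, both chosen after seeing the data, 521 and 389. Of the genes named for this comparison, 15 lost their call with all 4 groups in a single fit, 7 of them among the 8 hair genes named first, 7 lost it with the muscle level and 6 with Xist. Cxcl13 also lost it without any 1 of the F1 replicates or FVB replicate 4, Lamb3 without F1 replicate 1, 3 or 4, and Mki67 and Col5a1 without F1 replicate 3. With the replicate block the immediate early and circadian lists passed as well (camera adjusted p = 0.0301 and 0.0350).

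No single gene in the tail epidermis was called against papilloma number across the 71 backcross mice. The smallest limma adjusted p was 0.232, and 1316 genes had an unadjusted p under 0.05, a number reached in 8 of 100 orders of the papilloma numbers, the real one included (median of the others 472, highest 1825). Genes of cell division were higher in mice with more papillomas as a list (median slope 0.11 log2 units per doubling of papillomas + 1, camera adjusted p = 2.05e-16). None of its 25 members was called over all genes, 16 were called when adjusted over the list alone, and the list had an adjusted p = 0.265 with an estimated correlation. The mean level of this list correlated with papilloma number at r = 0.344 (permutation p = 0.00321, 0.0803 adjusted over 25 lists) and rho = 0.323 (p = 0.00611, adjusted 0.0703). Without the 2 mice with 35 and 23 papillomas r was 0.351. Stress keratin and hyperplasia genes followed (median slope 0.25, camera adjusted p = 1.37e-08; adjusted p = 0.265 with an estimated correlation; 7 of 14 adjusted over the list alone), with r = 0.318 (adjusted permutation p = 0.0946). Immediate early genes went the other way (median slope -0.09, camera adjusted p = 3.96e-08; adjusted p = 0.295 with an estimated correlation; 2 of 19 lower adjusted over the list alone), with r = -0.280 (adjusted permutation p = 0.134). The cornified envelope list (slope upward) and the circadian list (downward) also passed camera, each with an adjusted p = 0.840 with an estimated correlation and no member called over the list alone.

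Of the seed genes fixed in advance, Vdr was lower in mice with more papillomas and Lgr5 showed no relation. Vdr had r = -0.342 (permutation p = 0.00369, 0.00738 adjusted over the 2 seed genes) and rho = -0.372 (p = 0.00159), and r = -0.335 without the 2 mice with the most papillomas. Its other probe set gave r = -0.300. Over all genes tested, its limma adjusted p was 0.296. The adjustment over 2 genes holds only if these were chosen without regard to these arrays, which cannot be checked here. Lgr5 had r = -0.00539 (permutation p = 0.964). The genes with the smallest p, none of them called, were Ell2, a transcription elongation factor (r = 0.458), Anapc15 (0.448, 2 of 4 probe sets in that direction), Fer (0.437), the arginase Arg1 (0.418), Gsta4 (0.415), Camk2n2 (0.415), Ska1 (0.405), Higd1a (0.402), Ndufc1 (0.401) and Aox4 (0.402) upward. Downward they were Msl2 (r = -0.494, 2 of 3 probe sets in that direction), Pdik1l (-0.453), Sinhcaf (-0.444), Tenm2 (-0.441), Csrnp2 (-0.433), Phf24 (-0.432, 1 of 3 probe sets in that direction), Clk4 (-0.427), Prickle2 (-0.420), Prag1 (-0.419, 1 of 2 probe sets in that direction) and Lonrf1 (-0.418). By list the leading members were Mcm5 of the replication helicase (r = 0.385), Sprr2h (0.363), Sprr2d (0.363), Egr2 (-0.383), Npas2 (-0.314) and Sox9 (-0.309, 2 of 3 probe sets in that direction). The leading macrophage, T cell, melanocyte and fibroblast genes, Laptm5 (4 of 5 probe sets in that direction), Itgae, Oca2 and Vim, had r from 0.143 to 0.211. By Pearson and by Spearman alike, 27 of the 32 relations had an adjusted permutation p under 0.05. All 32 correlations kept their sign without the 2 mice farthest from the median. Since these genes were chosen by their p, their permutation p-values are not evidence beyond the limma adjusted p of 0.232 or more.

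**Figure D2:**
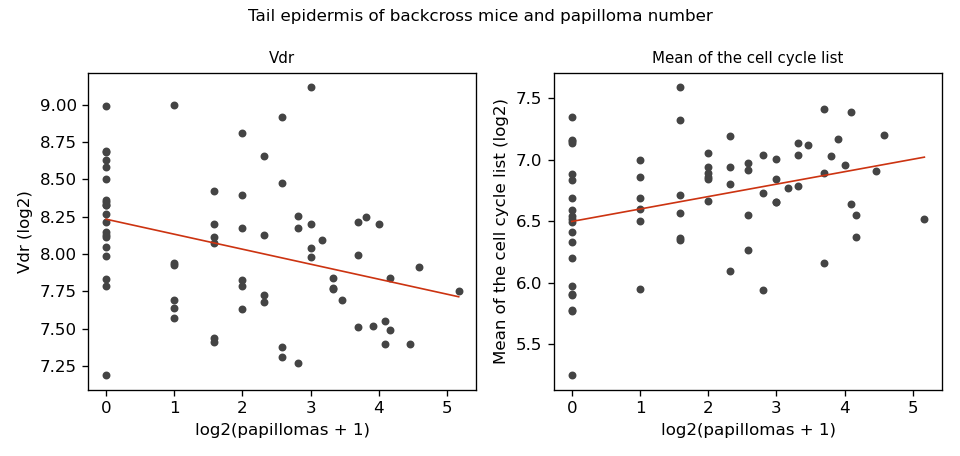
Log2 level of Vdr (left) and mean log2 level of the cell cycle list (right) in tail epidermis against log2(papillomas + 1) in 71 backcross mice, each point a mouse, with least-squares lines. Vdr falls (r = -0.342) and the cell cycle level rises (r = 0.344) with papilloma number, with wide scatter at every number.

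Lgr5 varied together with the hair program across backcross mice. Of 35 hair follicle genes, 33 rose with Lgr5 and none fell (median slope 1.98, camera adjusted p = 1.81e-49; adjusted p = 0.00729 with an estimated correlation), with Krt28 at r = 0.820 and Padi3, which modifies hair proteins, at r = 0.819. The mean hair list level followed Lgr5 at r = 0.766 and rho = 0.795 (both permutation p = 1e-05, the smallest possible), and at r = 0.747 without the 2 mice farthest from the median of Lgr5. The hair list had the smallest camera adjusted p for Lgr5 in these same mice, so its mean is no separate evidence. Wnt signalling genes rose in 17 of 28 cases (camera adjusted p = 4.84e-08; 0.00126 with an estimated correlation), Fzd7 at r = 0.711, and follicle stem cell markers in 9 of 15 (camera adjusted p = 1.26e-05; adjusted p = 0.0124 with an estimated correlation), Lhx2 at r = 0.833. Fibroblast markers rose in 15 of 19 cases (camera adjusted p = 1.53e-12; adjusted p = 0.112 with an estimated correlation), Col1a1 at r = 0.740. Cell cycle genes (14 of 25), sebaceous genes (7 of 18) and melanocyte markers (6 of 10) rose and circadian genes (7 of 17) and interferon response genes (6 of 20) fell, as did 3 of 19 immediate early genes, of which 1 rose; their adjusted p ran from 0.289 to 0.743 with an estimated correlation.

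The closest partners of Lgr5 were Adgra3 (r = 0.852, 1 of 3 probe sets in that direction), the zinc transporter Slc39a10 (0.843), Lap3 (0.819), Cnpy4 (0.818), Ptprv (0.813), Bambi, an inhibitor of TGF-beta signals (0.809), and the homeobox gene Msx2 (0.801), beside Lhx2, Krt28 and Padi3. The most negative were Phf7 (r = -0.716), Fgfr3 (-0.683), Wdr91 (-0.679), Vegfd (-0.677), Rps25 (-0.662), Sh2d3c (-0.647), Qars (-0.643), Pde1b (-0.633), Slc25a28 (-0.628) and Snhg8 (-0.624). Further list members were Scd2 (r = 0.517), Mlana (0.486), Bub1 (0.446, 1 of 2 probe sets in that direction), Cry1 (-0.486), Myc (-0.419), C1qb (-0.396), Mx2 (-0.392) and Lat (-0.381). Of 31 relations, 30 had an adjusted permutation p under 0.05 for r and for rho, Vdr being the exception, and all 31 kept their sign without the 2 mice farthest from the median of Lgr5. These genes were chosen by their p. In all, limma called 3788 genes, 2214 rising and 1574 falling with Lgr5; after quantile normalization 1756 rose and 2113 fell. With the other probe set of Lgr5, which is near the floor at 3.34 ± 0.21 (SD, n = 71) and correlates with the used probe set at -0.108, 1 gene was called. With the first 3 principal components as covariates 155 genes were called.

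**Figure D3:**
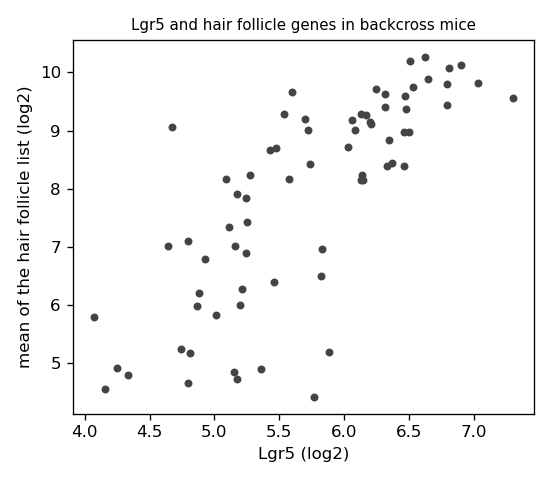
Mean log2 level of the hair follicle list against the log2 level of Lgr5 in 71 backcross mice, each point a mouse. The hair follicle level spans 4.42 to 10.27 and rises with Lgr5 (r = 0.766).

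Mice with high Vdr had lower levels of macrophage and dendritic cell genes. Of 10 T cell markers none was called over all genes and 2 were lower when adjusted over the list alone (median slope -0.09, camera adjusted p = 0.0860). A difference between these cell types was not tested. Of 21 macrophage, dendritic and Langerhans cell markers, 10 fell with Vdr and none rose (median slope -0.55, camera adjusted p = 5.54e-10; adjusted p = 0.104 with an estimated correlation). The mean of that list had r = -0.445 and rho = -0.427 with Vdr (permutation p = 0.000120 and 0.000130, adjusted 0.000280 and 0.000303 over 7 relations), and r = -0.400 without the 2 mice farthest from the median of Vdr. That list had the smallest camera adjusted p of the 25 lists for Vdr in these same mice. Its mean is therefore no separate evidence, and adjusting over 7 relations does not cover the choice among lists. Stress keratin and hyperplasia genes fell in 7 of 14 cases (camera adjusted p = 6.08e-06; adjusted p = 0.152 with an estimated correlation), among them the cytokine Il1f6 (r = -0.504), and 7 of 15 antigen presentation genes (camera adjusted p = 0.00109; adjusted p = 0.275), among them Psmb10 (r = -0.562). Immediate early genes rose in 7 of 19 cases (camera adjusted p = 8.02e-09; adjusted p = 0.104), Fosl2 at r = 0.574, follicle stem cell markers in 5 of 16 (adjusted p = 0.0970), Sox9 at r = 0.533, circadian genes in 5 of 17 (adjusted p = 0.104), Nfil3 at r = 0.539, basal epidermis genes in 4 of 12 (adjusted p = 0.104), Lama3 at r = 0.518 with 1 of 2 probe sets in that direction, and Wnt genes in 3 of 28 (adjusted p = 0.104), Fzd6 at r = 0.538. Cytokines (4 of 20 lower, adjusted p = 0.148) included Tslp at r = -0.492, and cornified envelope genes (4 of 32 lower, adjusted p = 0.388) included Rptn at r = -0.504 with 2 of 3 probe sets in that direction. The adjusted p-values from the stem cell markers on are those with an estimated correlation. Vitamin D receptor pathway genes (1 of 11 called) also passed camera upward, and interferon response (none of 20), cell cycle (1 of 25), mast cell (2 of 10), B cell (none of 4) and muscle genes (none of 19) downward, at an adjusted p from 0.0970 to 0.709 with an estimated correlation.

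The closest partners of Vdr were Irx2 (r = 0.696), the transcriptional repressor Bcl6 (0.677), Tenm2 (0.679, 2 of 4 probe sets in that direction), Sinhcaf (0.653), Arrdc3 (0.620), Gadd45g (0.620), Arid5b (0.616, 4 of 5 probe sets in that direction), Celsr1 (0.613), Luzp1 (0.613) and the cell cycle inhibitor Cdkn1a (0.595). Among the most negative were Mien1 (r = -0.617), Arhgdib (-0.616), Tnfaip8l2 (-0.611), Ptpro (-0.610), Slamf9 (-0.609), Sash3 (-0.579), Gstp1 (-0.570), Snrnp25 (-0.569), Myo1g (-0.568) and Rgs19 (-0.560). The pan-leukocyte marker Ptprc had r = -0.531 (1 of 2 probe sets in that direction), the mast cell gene Ms4a2 -0.370 (not called without the 2 mice farthest from the median of Vdr) and Ifih1, which was not called, -0.317. Of 33 relations, 32 had an adjusted permutation p under 0.05 for r and 33 for rho. That with Lgr5 lay at the limit for rho, with 0.0492 here and 0.0511 among the relations of Lgr5, from separate permutations. All 33 kept their sign without the 2 mice farthest from the median of Vdr. Vdr and Lgr5 correlated at r = 0.200 (permutation p = 0.0955), with 1 of 2 Lgr5 probe sets in that direction. In all, limma called 1149 genes with Vdr, 568 rising and 581 falling. The split was 725 and 420 with equal array medians and 595 and 901 after quantile normalization, and with papilloma number as a covariate 755 genes were called.

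Set against untreated mice, the tail skin of backcross mice treated on the back had lower levels of hair genes. Against the mean of FVB and F1, levels of macrophage, endothelial and blood, and adipocyte genes were higher. For muscle genes the direction depended on the untreated group taken as reference. These are levels across separately scaled arrays, given relative to the median over genes and without a test. The hair list lay at a median of -1.94 from the mean of FVB and F1, below all of 10000 random lists matched on level (percentile 0). Genes of the hair list vary together and those of random lists need not, so this percentile does not measure chance. The fibroblast list lay at -0.49, the melanocyte list at -0.43, the stem cell list at -0.42, the cornified envelope list at -0.34 and the cell cycle list at -0.27. The Wnt and sebaceous lists lay at -0.26 each. Macrophage, dendritic and Langerhans markers lay at 0.49, endothelial and blood genes at 0.53, adipocyte markers at 0.48, antigen presentation at 0.39, mast cell markers at 0.33, immediate early genes at 0.31 and interferon response genes at 0.24. T cell markers lay at -0.27, with 1 of 10 above the median gene, and B cell genes at -0.02. Muscle markers lay at 1.04, but at -0.89 against F1 alone and at 0.61 without F1 replicate 2. Of the lists, only hair, muscle and macrophage were set against FVB alone or F1 alone. In F1 the endothelial and blood list lay 0.64 above FVB relative to the median gene, the adipocyte list 0.60 and the fibroblast list 0.83. The levels of these lists in the backcross therefore depend on the reference. The macrophage list lay at 0.29 without FVB replicate 2. The largest single levels above were Cxcl13 (3.60, though 1.85 against FVB alone and 5.35 against F1 alone), the neutrophil protein Lcn2 (2.83), the stress keratin Krt6b (2.48), Myhas (2.23), Lrg1 (2.16), Hbb-b2 (2.14), the heme enzyme Alas2 (2.14) and Fam107a (2.11). The stress keratin and hyperplasia list, which holds Lcn2 and Krt6b, lay at only 0.03, with 7 of 14 genes above the median gene. Krt6b had an SD of 2.08 in FVB and 2.77 in the backcross. Below lay Krtap5-2 (-2.90), Krtap5-3 (-2.90), Col1a1 (-2.82), Krtap19-3 (-2.74), Krtap13 (-2.74), Krtap19-9b (-2.73), Prr9 (-2.72) and Krtap19-2 (-2.62).

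Backcross mice varied more than untreated mice of a group, and their spread was larger for genes with larger parental differences. The median SD of a gene was 0.33 over the 71 backcross mice and 0.20 within the untreated groups, and the median ratio was 1.61. The ratio was 1.78 for genes at least 2-fold apart between the parents and 1.51 for genes not called between them. The spread within the untreated groups also decides which genes are called, so the choice of genes by itself pushes these ratios apart. The median backcross SD alone was 0.54 and 0.32 for these sets of genes. Apart from Xist and the Y-linked Eif2s3y, hair genes such as Krt33a (SD 2.85), Krtap15 (2.82) and Krtap16-3 (2.81) varied most, together with Krt6b (2.77). Across genes, which are not independent replicates, the backcross SD and the size of the parental difference had a Spearman rho of 0.385, and of 0.462 with the difference between F1 and FVB. Treatment and scaling also differ between these sets of mice.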

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

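The tests of probe mismatch, of muscle tissue, of RNA degradation behind the muscle genes and of chance over the lists, and the fits with the muscle level, were chosen only after the results were seen. Single arrays far from the other 3 of their group were found in 12 of 156 groups examined, where chance gives about 7.8 (about 1 in 20). In F1 replicate 2 the muscle genes Myl2 (6.11), Myh7 (6.09), Mb (8.32) and Klhl41 (5.35) lay far below the other F1 arrays. In FVB replicate 2, Cxcl13 (4.39), Lyz1 (10.24), Cldn5 (6.94) and Gstp1 (10.65) were lower and the pigment genes Dct (9.78) and Mc1r (7.42) higher than in the other FVB arrays. Vdr was higher in F1 replicate 4 (9.24) and Krt86 lower in F1 replicate 3 (11.55).

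Chance was tested for the strain comparisons by other splits of the mice. For Spretus against FVB (5694 calls, highest other 0) and F1 against FVB (1794, highest other 0), 1 of 35 splits of the 8 mice, the real one, gave as many calls. This makes chance unlikely without excluding it, since other splits mix strains within a group, which widens the spread and lowers the calls. Muscle content and sex, which differ between groups, are not addressed. For F1 against the mean of the parents 1 of 100 splits did (1156, highest other 3). Those splits did not part F1 and Spretus arrays by their pairs, so no conclusion is drawn from them. For F1 against Spretus the numbers were treated as pairs, and the 8 splits that part every pair, the real one included, are too few for a share under 5 percent (3844, highest other 0). Chance is also unlikely for Lgr5 and Vdr, where 1 of 100 orders of the mice, the real one, reached 3788 (highest other 5) and 1149 (highest other 1). For papilloma number 8 of 100 orders gave 1316 or more genes at an unadjusted p under 0.05 (highest other 1825), so chance is not excluded.

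Hair follicle genes were far lower in Spretus and higher in F1 than in FVB. Over all 35 measured members F1 lay at a median of 1.70 log2 units above FVB relative to the median gene (interquartile range 0.90). Probe mismatch to the Spretus sequence would place F1 at or below FVB, so it was no candidate for the higher F1 level. That value restates the pattern and is no separate test. Mismatch stays open as a source of the low Spretus level. Mismatch alone would place F1 at the mean of the linear parental signals, and over the 29 members at least 2-fold apart F1 lay 2.73 above that mean (interquartile range 0.69), but this follows from F1 lying above FVB and would also arise if F1 samples held more hair follicle. In the backcross, follicle growth that differs between mice could make the list vary together, but its level followed the cell cycle list only at r = 0.193 (permutation p = 0.106), too weak to decide. Hair cycle stage, age and strain genetics stay open as untested, because the labels used here give no stage.

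Skeletal muscle genes were high in Spretus, in 3 of 4 F1 mice and in part of the backcross. Muscle tissue in the samples would keep these genes in a fixed ratio, and their median pairwise correlation over 71 mice was 0.926, consistent with it. Acta1 averaged 6.21 in FVB, 12.06 in F1 and 12.82 in Spretus. RNA degradation as the source would tie the muscle level to the actin 3-prime to 5-prime ratio, with which it had r = -0.206, below what that would need. Whether the strains differ in how much muscle lies under tail skin, or how the skin was taken, stays open as untested. With the muscle level as a covariate the calls between Spretus and FVB came to 567 and those between F1 and FVB to 21, but the level differs between these groups, so strain differences are removed with it.

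The cell cycle list moved upward with papilloma number by camera, but none of its 25 members was called over all genes and its adjusted p was 0.265 with an estimated correlation. For its mean level the partial correlation was 0.324 given the actin and GAPDH ratios, 0.341 given the hair follicle level and 0.353 given the muscle and macrophage levels, each with a standard error of 0.12, which argues against RNA degradation, follicle content and other tissue, as far as these measure them, as the whole cause. The permutation p adjusted over the 25 lists was 0.0803, so chance is not excluded. A higher division rate in the uninvolved tail skin of tumor-prone mice, or a response to treatment or tumors, may underlie it, and neither was tested.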

How the results depend on the processing

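Fits with Xist as a covariate in the strain comparisons, those with muscle, hair or RNA quality covariates, and those without the 4 least similar arrays were chosen only after the data were seen. Among single named genes, 2850 of 2975 values under other settings kept their direction and side of the threshold, 94 lost the call, 5 gained it, 4 moved and 22 reversed. The cause of the changes below was not tested, except where fewer samples or more probe sets tested account for them. The count of 0 for papilloma number held in every setting run.

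With every probe set by itself the calls were 9923 for Spretus vs FVB, 2812 for F1 vs FVB, 6586 for F1 vs Spretus and 6927 for Lgr5. With all 4 groups in a single fit, where the more variable backcross sets the spread, they were 3496, 110, 1567 and, for F1 against the mean of the parents, 198. The level of Xist as a covariate left 1147 for F1 vs FVB and 521 against the mean of the parents; the muscle level left 567 for Spretus vs FVB, 21 for F1 vs FVB and 389 against the mean of the parents. For Lgr5 the first 3 principal components left 155, the hair level 1214 and the other probe set 1. For Vdr papilloma number as a covariate left 755, and leaving out the 4 arrays least like the others 737. Lists past camera with an estimated correlation numbered 0 for Spretus vs FVB (6 otherwise), 0 for F1 vs FVB (7), 0 for F1 vs Spretus (7), 2 against the mean of the parents (11), 0 for papilloma number (5), 3 for Lgr5 (10) and 0 for Vdr (16). The rho of backcross spread with parental difference was 0.448 without a filter, 0.368 with the lowest 50% of genes left out and 0.402 with the mean over probe sets.

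With the replicate block the counts were 5579, 1724, 3718 and 1165 for Spretus vs FVB, F1 vs FVB, F1 vs Spretus and F1 against the mean of the parents, and 7, 6, 7 and 13 lists passed, so the pairing moved no count by over 1.5 times. It changed the call of 4 lists and of no named gene. The cell cycle list passed camera for Spretus vs FVB (adjusted p = 0.0352), the stress keratin list no longer did for F1 vs FVB (0.0521), and the immediate early (0.0301) and circadian lists (0.0350) did against the mean of the parents. Of the 4 F1 arrays, 2 correlated best with the Spretus array of their own number; of the 4 FVB arrays, 1 did with F1 and 2 with Spretus.

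Leaving out 1 untreated array at a time gave 4988 to 5862 calls for Spretus vs FVB, 1160 to 2079 for F1 vs FVB (lowest without FVB replicate 3), 3008 to 4138 for F1 vs Spretus and 693 to 1674 against the mean of the parents (lowest without F1 replicate 3). For the treated levels it gave -2.04 to -1.86 for the hair list, 0.61 to 1.23 for the muscle list (lowest without F1 replicate 2) and 0.29 to 0.60 for the macrophage list (lowest without FVB replicate 2). The muscle list lay at 3.21 against FVB alone and at -0.89 against F1 alone.

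Reversals were of single genes. With the other, dim probe set of Lgr5 the slopes became -0.0706 for Lhx2, -0.47 for Lap3, -0.21 for Bambi, -0.0490 for Ptprv, -0.17 for Msx2, 0.12 for Phf7, 0.0255 for Vegfd, 0.46 for Rps25, 0.20 for Wdr91, 0.13 for Qars, 0.22 for Pde1b, 0.24 for Sh2d3c, 0.0659 for Slc25a28, -0.11 for Fzd7, -0.0816 for Bub1, 0.13 for Mx2, -0.35 for Mlana, 0.33 for C1qb and -0.15 for Vdr, none called. Myc became 0.11 with the 3 principal components, Mb -0.13 in Spretus vs FVB with the muscle level, and Lgr5 0.13 with any papilloma against none.

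Linkage of neighbouring genes was planned and not run, since gene positions were not used here. For the treated backcross the planned fits with array weights, without trend, with all 4 groups and with every probe set by itself were not run, since no test was made. A low signal over background limits the dim genes that the filter removes.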

Other observations

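The division of the clustered genes into keratin-associated protein genes and others was chosen only after the result was seen. Outside the hair, pigment and muscle genes and the 3 other lists that passed, no list passed camera between Spretus and FVB, which does not show that these lists were alike in both. The stress keratin list had a median of -0.91 relative to the median gene, the cell cycle list -0.41, the adipocyte list 0.93 and the endothelial and blood list 0.68. Of 20 interferon response genes 7 were higher and 1 lower (camera adjusted p = 0.176), and 11 of 25 xenobiotic metabolism genes were higher and 6 lower (0.464). Cornified envelope genes went both ways, with 11 of 32 higher and 6 lower (0.891), as did stress keratin genes, with 3 of 14 higher and 6 lower (0.283), and cytokines, with 5 of 20 higher and 2 lower (0.753). Cell cycle genes were lower in 5 of 25 cases and higher in 1 (0.0559, or 0.0352 with the replicate block, where the list passed). Few members of the immune lists were called, with 2 higher and 1 lower of 21 macrophage, dendritic and Langerhans markers (0.727), 1 of 10 T cell markers higher (0.906), 2 of 4 B cell genes higher (0.753), 1 higher and 1 lower of 10 mast cell markers (0.753) and 4 of 15 antigen presentation genes higher (0.891). The vitamin D receptor pathway (2 of 12 higher, 1 lower; 0.727), Wnt genes (7 of 28 higher, 5 lower; 0.891), basal epidermis (3 of 12 higher, 1 lower; 0.870), immediate early genes (4 of 19 higher, 2 lower; 0.891), the circadian list (2 of 17 higher, 3 lower; 0.753), endothelial and blood genes (3 of 13 higher; 0.210), adipocyte markers (3 of 8 higher, 1 lower; 0.753) and the list of Xist and Y-linked genes (none of 2; 0.891) did not pass either.

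A backcross mouse carries either 2 FVB copies of a locus or 1 of each kind, so a gene set by its own locus would divide the mice into FVB-like and F1-like animals. This hypothesis was tested on the 1020 genes called at least 1.5-fold apart between F1 and FVB, leaving out the hair and muscle lists. The variance in excess of unaffected genes of similar level was divided by that expected from an even division. This excess ratio had a median of 0.748 (quartiles 0.416 and 1.25), with 316 genes under 0.5 and 236 over 1.3. A locally acting locus at part of the genes could give this median. Muscle content that differs between mice could as well, since only members of the muscle list were left out. The ratio does not tell these apart. Mice fell into 2 clusters at 52 of the 1020 genes and at 1 of 1020 matched genes, a ratio of 52 that rests on that single matched gene. Of the 52, 13 are keratin-associated protein genes outside the hair list, whose median excess was 3.94, more than a single locus of this size can give. At the other 39 the median excess was 1.15, the smaller cluster held a median of 42.1% of mice, and the clusters lay 2.00 apart where F1 and FVB differ by 1.70. A gene counted as clustered only if 2 clusters fitted clearly better than 1 and the smaller held a minimum share of mice. The values at these 39 genes are therefore partly set by that rule. Over all 1003 genes that are not keratin-associated protein genes the median excess was 0.740. The cluster gaps and the F1 differences come from separately scaled arrays. Plau, the urokinase gene, and Scd3, a desaturase of sebaceous lipids, are examples chosen after their values were seen, with clusters 3.09 and 4.56 apart against F1 differences of 3.12 and 3.82. Genotypes were not used here, so which mice carry which allele stays open.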
